A study of Homo sapiens with 30 samples.

How the data were processed

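The deposited table held 54613 probe sets of 30 HG-U133 Plus 2.0 arrays, 3 per line in 10 lines, and 0 columns of other series. Per the series design text and the submitters' processing notes, the authors computed the log2 values by RMA, which corrects background, normalizes quantiles and summarizes the probes of a probe set. The version of RMA and the chip definition are not given in the sources used here. Values spanned 1.91 to 14.62. No further normalization was applied. Per the series design the 3 arrays of a line are biological triplicate cultures, and their number limits the precision.

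Probe sets were assigned to genes with the platform annotation: 41091 had 1 symbol, 1801 several and 11721 were not listed there. Probe sets with several symbols or none were left out, and 0 symbols were updated. For each of the 19775 genes, of which 10523 had more than 1 probe set, the probe set with the highest mean over all arrays was taken. A gene was tested if that probe set exceeded the median of all values (5.013) on at least 3 arrays, which left 13137 genes.

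A linear model with a mean per line was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3 (20 residual degrees of freedom). The 16 comparisons were contrasts of this fit with empirical Bayes moderated variances, and p values were adjusted by Benjamini and Hochberg within each comparison. A gene changed at an adjusted p under 0.05. Genes changed at least 2-fold and genes whose arrays did not overlap between the lines were counted beside it. SE is the moderated standard error of a log2 difference, with 3 arrays per line. NSD2 was also read on all 6 probe sets, adjusted over probe sets.

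Genes were named by rule. These were the 10 genes highest and 10 lowest in PAR against TKO, WT against TKO and WT against CDM and the 5 and 5 of other comparisons, among genes past the threshold without overlap of arrays. Added were NSD2, the reported NSD2 targets and up to 4 members of each list that passed. The plasma cell genes and the genes given for H762Y replicate 1 were chosen after their values were seen.

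Each comparison was tested on 24 gene lists and 5 marker lists with camera of limma and its preset correlation between genes, adjusted over the 29 lists. The same test with a correlation estimated from the data is given beside it. The list of ribosomal proteins was a reference set. Members of a list were counted by the gene tests and also after adjustment over the list alone.

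Comparisons against TKO share arrays with PAR against TKO. The correlation expected from this alone was taken from 100 simulations of unchanged lines with the fitted variances. Whether replicate numbers pair the arrays of 2 lines was checked once, from the correlation of the residuals of arrays with equal numbers. They paired in PAR against TKO, CDM against TKO, 526-1365 against 526-1240, 526-1365 against WT, MMSET1 against TKO and WT+MMSET1 against WT.

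The comparisons, the filter, the threshold and most of the other settings tried were chosen before the data were examined. A fit without H762Y replicate 1 and a fit of 2 lines with the replicate number as a block were added after the data were seen. Real and regrouped arrays were compared over all 10 splits of each 6 arrays. On simulated data with 200 changed genes of 13137, the pipeline recovered 58% of 1.5-fold and 91% of 2-fold changes with 14 false calls, and 0 calls in an unchanged comparison.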

Results

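Gene expression was measured on Affymetrix HG-U133 Plus 2.0 arrays in KMS11, a human multiple myeloma cell line whose chromosomal translocation drives high expression of NSD2 (also called MMSET), a histone H3 methyltransferase. The 30 arrays fall into 10 lines of 3 separate cultures each. PAR is the parental line and TKO the line described as an NSD2 knockout. The other 8 are knockout cells that received a transgene. WT carries full-length NSD2, CDM the catalytic dead mutant, and H762Y full-length NSD2 with a substitution in a PHD finger, a small zinc-binding domain. The 526-1240 and 526-1365 lines carry fragments named by their residues. Both start after the first PWWP domain and the HMG box, and the shorter ends before the last PHD finger. MMSET1 carries MMSET I, the short isoform that lacks the catalytic SET domain, and WT+MMSET1 and CDM+MMSET1 carry it beside the full-length protein. All values are the authors' log2 RMA values, so a difference of 1 is a 2-fold change. Each line is given by its mean ± SD of n = 3 arrays, and this number limits the precision. Array medians lay between 4.986 and 5.039. RMA values carry no call of presence, and a mean under 5.013, the median of all values, is called dim here: a difference from a dim mean is one of array values, and the change of the RNA itself is not measured.

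The first principal component, with 54.8% of the variance, parted the lines by NSD2 form. PAR, WT, WT+MMSET1 and both fragment lines lay between -40.8 and -11, and TKO, CDM, MMSET1, CDM+MMSET1 and replicates 2 and 3 of H762Y between 22.5 and 38.7. H762Y replicate 1 lay at -7.16. It correlated with the other two H762Y arrays at 0.958 and 0.961 across genes, while those correlated with each other at 0.998, and its closest array was WT+MMSET1 replicate 1 (0.981). The PAR arrays had the lowest values on the second component, -24.6 to -53. PAR replicate 1 correlated with WT replicate 3 at 0.9794, between its correlations with PAR replicate 2 (0.9828) and PAR replicate 3 (0.9704).

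**Figure D1:**
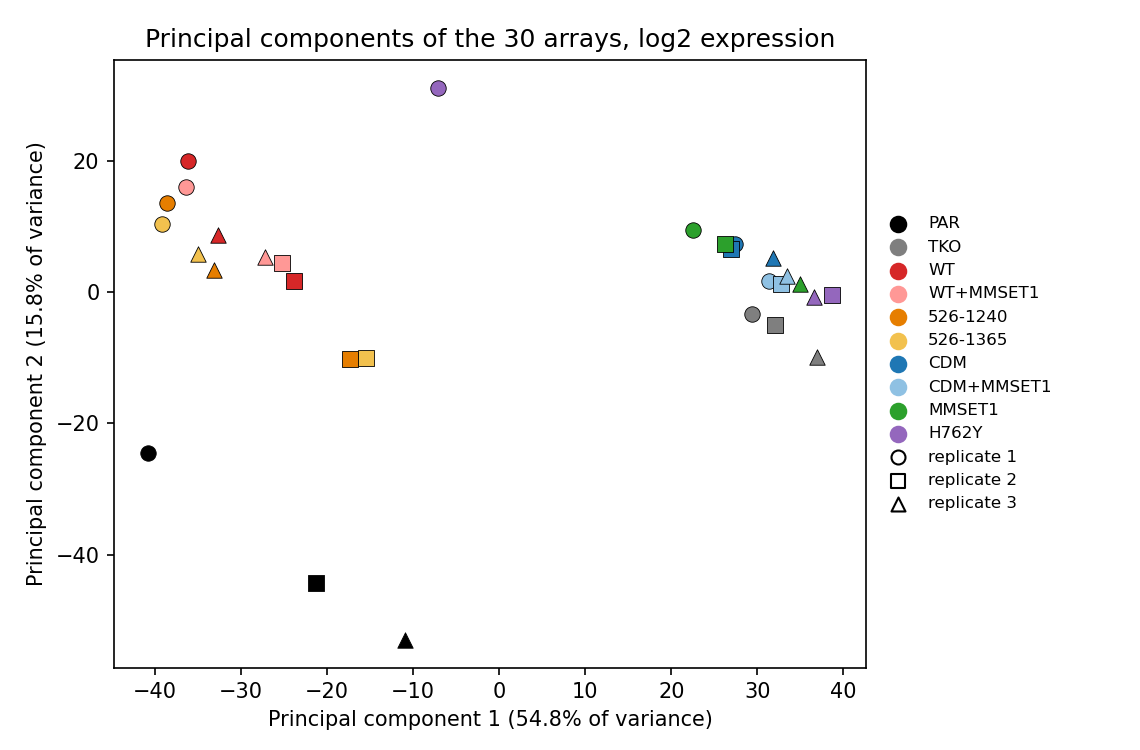
Scores of the 30 arrays on principal components 1 (horizontal, 54.8% of the variance) and 2 (vertical, 15.8%) of log2 expression, coloured by line, with symbols for replicates 1 to 3. The active NSD2 lines sit left of 0, the knockout and inactive lines at 22.5 to 38.7, and H762Y replicate 1 alone at -7.16.

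NSD2, the gene described as knocked out in TKO, still gave signal there on all 6 of its probe sets. Probe set 209054_s_at read 10.61 ± 0.042 in PAR and 10.18 ± 0.111 in TKO, a difference of 0.43 (SE 0.0974, adjusted p = 0.00216 over probe sets). Differences of 0.98 and 0.81 on 222778_s_at and 222777_s_at also passed (adjusted p = 0.00208 and 0.000336), while the differences on 223472_at (0.39), 209053_s_at (0.10) and 209052_s_at (-0.22) did not. Probe set 223472_at was higher than in TKO in all 6 lines tested for it, by 0.54 in CDM, 0.57 in MMSET1, 0.61 in 526-1240, 0.65 in 526-1365, 0.71 in WT and 0.79 in H762Y. Probe set 209052_s_at fell by 1.20 in 526-1240 against TKO, fell in MMSET1 (7.206 ± 0.322 against 8.202 ± 0.18 in TKO) and was 0.57 higher in 526-1365 (adjusted p = 0.00023, 0.00321 and 0.0491). Which part of the transcript was deleted, and which parts the transgenes carry on the array, is not given in the sources used here. A probe set outside a deleted part checks nothing, so the arrays alone do not test the knockout label. They also do not show that TKO cells lack all NSD2.

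The parental and knockout lines were compared in PAR against TKO, where loss of NSD2 cannot be told apart from other differences of the knockout line. RRAS2, a RAS family GTPase reported as an NSD2 target, stood at 7.90 ± 0.210 in PAR and was dim in TKO at 3.04 ± 0.079 (log2 difference 4.87, SE 0.140, adjusted p = 4.63e-18). The genes with the largest excess in PAR were CR2, the complement receptor of B cells (5.52), the transcription factor FOXP2 (5.51), carbonic anhydrase CA2 (5.20), the collagen lysyl hydroxylase PLOD2 (5.04), LARP6 (4.89), the type IV collagen chain COL4A5 (4.88), RRAS2, the RNA-binding protein IGF2BP2 (4.74), the amino acid transporter SLC6A15 (4.70) and FGF13 (4.50). TGFA, a ligand of the EGF receptor, was higher in PAR and dim in TKO (3.97, SE 0.419, adjusted p = 7.78e-08), although its other probe set changed by 0.41. All 10 genes of largest excess were dim in TKO. MET, the HGF receptor, was at 5.43 ± 0.136 and 5.38 ± 0.074 on its brighter probe set (adjusted p = 0.694), and its dimmer probe set was 2.01 higher in PAR.

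In the other direction, 5 of the 10 genes lowest in PAR carried HLA class II symbols. Proteins of this class present peptides to helper T cells. HLA-DPA1 read 5.003 ± 0.214 in PAR and 10.85 ± 0.030 in TKO, and so was dim in PAR (log2 difference -5.85, SE 0.140, adjusted p = 2.01e-19). HLA-DQA1 (-4.95), HLA-DRB4 (-4.88), HLA-DPB1 (-4.66) and HLA-DRB6 (-3.77) followed, with the fungal glucan receptor CLEC7A (-4.64), ADTRP (-4.63), the inhibitory collagen receptor LAIR1 (-4.55), the G protein-coupled receptor P2RY10 (-4.28) and KIAA1549L (-3.73). CLEC7A, ADTRP and LAIR1 were dim in PAR too. Probe sets of near-identical HLA genes can share signal, so the value of a single DP, DQ or DRB gene is uncertain.

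Of 21 antigen presentation genes tested, 12 fell in PAR relative to TKO and 0 rose, 12 and 0 also when adjusted over the list alone. The list test gave an adjusted p = 2.06e-12 (adjusted p = 0.105 with an estimated correlation). Of the 3 reported NSD2 targets tested, RRAS2 and TGFA rose, 2 also when adjusted over the list alone (adjusted p = 0.000729, and adjusted p = 0.0163 with an estimated correlation). If these targets were chosen on such cells, the list is not independent evidence. Of 14 genes of RAS-MAPK output 5 rose in PAR (6 adjusted over the list alone), led by the feedback inhibitor SPRY2 (2.30, dim in TKO), the transcription factor ETV5 (1.45) and the phosphatases DUSP5 (1.33) and DUSP4 (0.92). Of 15 NF-kB targets 5 fell and 1 rose (6 and 1 adjusted over the list alone), with TNFAIP3 (-1.28), NFKBIE (-0.91), ICAM1 (-0.90) and LTB (-0.83) lowest. Both lists stood at adjusted p = 0.0498 and were not called with the replicate number as a block (adjusted p = 0.053 for RAS-MAPK output and 0.0663 for NF-kB targets). With an estimated correlation they had adjusted p = 0.188 and adjusted p = 0.105. DUSP5 missed the threshold without PAR replicate 1, at 0.94.

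Plasma cell genes went both ways between PAR and TKO. CD38 (1.504, dim in TKO), the surface proteoglycan SDC1 (0.89) and the BCMA receptor TNFRSF17 (0.54) were higher in PAR, while JCHAIN (-2.14), the joining chain of secreted IgM and IgA, and the coactivator POU2AF1 (-0.89) were lower. Of the 13 in the list 3 rose and 3 fell, 4 and 4 adjusted over the list alone, and the list was not called (adjusted p = 0.991). None of the 5 lists of markers of other cell types was called in any of the 16 comparisons. The nearest was the epithelial list in H762Y against WT (camera adjusted p = 0.104, with 1 of its 4 tested members lower). The signal filter left few markers to test: 4 each for T cells, fibroblasts and epithelium, 3 erythroid and 1 for monocytes and macrophages. The missing calls therefore do not exclude RNA of other cell types.

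Altogether 2928 of 13137 genes (22.3%) changed between PAR and TKO by limma at an adjusted p under 0.05, 1603 higher and 1325 lower in PAR. At least 2-fold changes numbered 658 higher and 173 lower. The 3 arrays of each line did not overlap at 4759 genes (36.2%, against 10% by chance). The split by direction depended on scaling: with each array centred on its median, 3189 genes passed and the share higher in PAR was 43.8% instead of 54.7%. Averaging a gene's probe sets gave 1302 higher and 1393 lower. Averaging also made differences smaller, to 2.79 for CR2, 1.85 for FOXP2, 2.54 for COL4A5, -1.85 for HLA-DQA1 and -2.92 for HLA-DPB1, with these calls kept.

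Re-expression of full-length NSD2 was read from WT against TKO. No line with an empty vector is among the groups analysed here. Every comparison of a transgene line with TKO may therefore also hold effects of transduction and selection. Each transgene was also read in a single line. A difference between transgene lines may therefore come from the lines themselves as well as from the proteins they carry. RRAS2 rose from a dim 3.04 ± 0.079 to 6.80 ± 0.162 (3.77, SE 0.140, adjusted p = 2.59e-15), and TGFA rose from a dim 3.74 ± 0.033 to 5.93 ± 0.939 (2.18, adjusted p = 0.000269). The largest rises were CLGN, a chaperone of the endoplasmic reticulum (5.74, 53.3-fold), the splicing regulator ESRP1 (4.80), THAP10 (4.49), the type IV collagen chain COL4A3 (4.48), GSAP (4.39), the mucin glycosyltransferase GALNT3 (4.36), MPPED2 (4.29), SLC6A15 (4.21), CA2 (4.20) and the non-coding LINC02806 (4.17). ADM, which encodes the vasodilator peptide adrenomedullin, fell to a dim 4.53 ± 0.354 (-4.32, adjusted p = 7.45e-08). It was followed by OLFML2B (-4.05), the acetylcholine receptor subunit CHRNA1 (-3.09), CLEC7A (-3.03), MYOF (-2.82), the globin gene HBD (-2.68), the chemokine receptor CCR1 (-2.56), the thioesterase ACOT7 (-2.56), the glycine receptor subunit GLRB (-2.49) and the small heat shock protein HSPB1 (-2.43). CLGN and THAP10 were the 2 of the 10 risen genes that were not dim in TKO, and CHRNA1, MYOF and GLRB were dim in WT. MET differed by -0.04 on its brighter probe set and rose by 1.33 on the dimmer.

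Of 18 cholesterol synthesis genes 10 fell in WT and 0 rose, 11 and 1 adjusted over the list alone, including the lanosterol synthase LSS (-1.32), PMVK (-1.21), TM7SF2 (-1.18) and the squalene epoxidase SQLE (-1.36). Antigen presentation genes fell at 9 of 21 and rose at 1 (10 and 2 adjusted over the list alone), with HLA-DMA (-1.14), the invariant chain CD74 (-0.93), HLA-DQB1 (-0.91) and HLA-DRB1 (-0.88) lowest. Both list tests gave adjusted p = 0.00392, with adjusted p = 0.801 and adjusted p = 0.71 with an estimated correlation. The antigen presentation list also fell in CDM against TKO, and 10 class II genes differed between WT and CDM by a median of 0.012. Of 3 reported NSD2 targets tested 2 rose, 2 adjusted over the list alone, but the list missed the threshold here (adjusted p = 0.0549). In total 5364 genes (40.8%) changed, 2824 higher and 2540 lower in WT, with 732 and 294 of them at least 2-fold. Averaging probe sets turned the balance to 2071 higher and 2762 lower, and testing every probe set to 3431 and 3825 with some genes in both. Averaged, TGFA rose by 0.81, GALNT3 by 2.31 and SLC6A15 by 2.13. The groups did not overlap at 6861 genes (52.2%, 10% by chance). Leaving out WT replicate 1 ended the call of ACOT7 (-2.09) and that of SQLE (-1.22), and SQLE was also lost without WT replicate 3 (-1.29), TKO replicate 2 (-1.33) or TKO replicate 3 (-1.36).

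**Figure D2:**
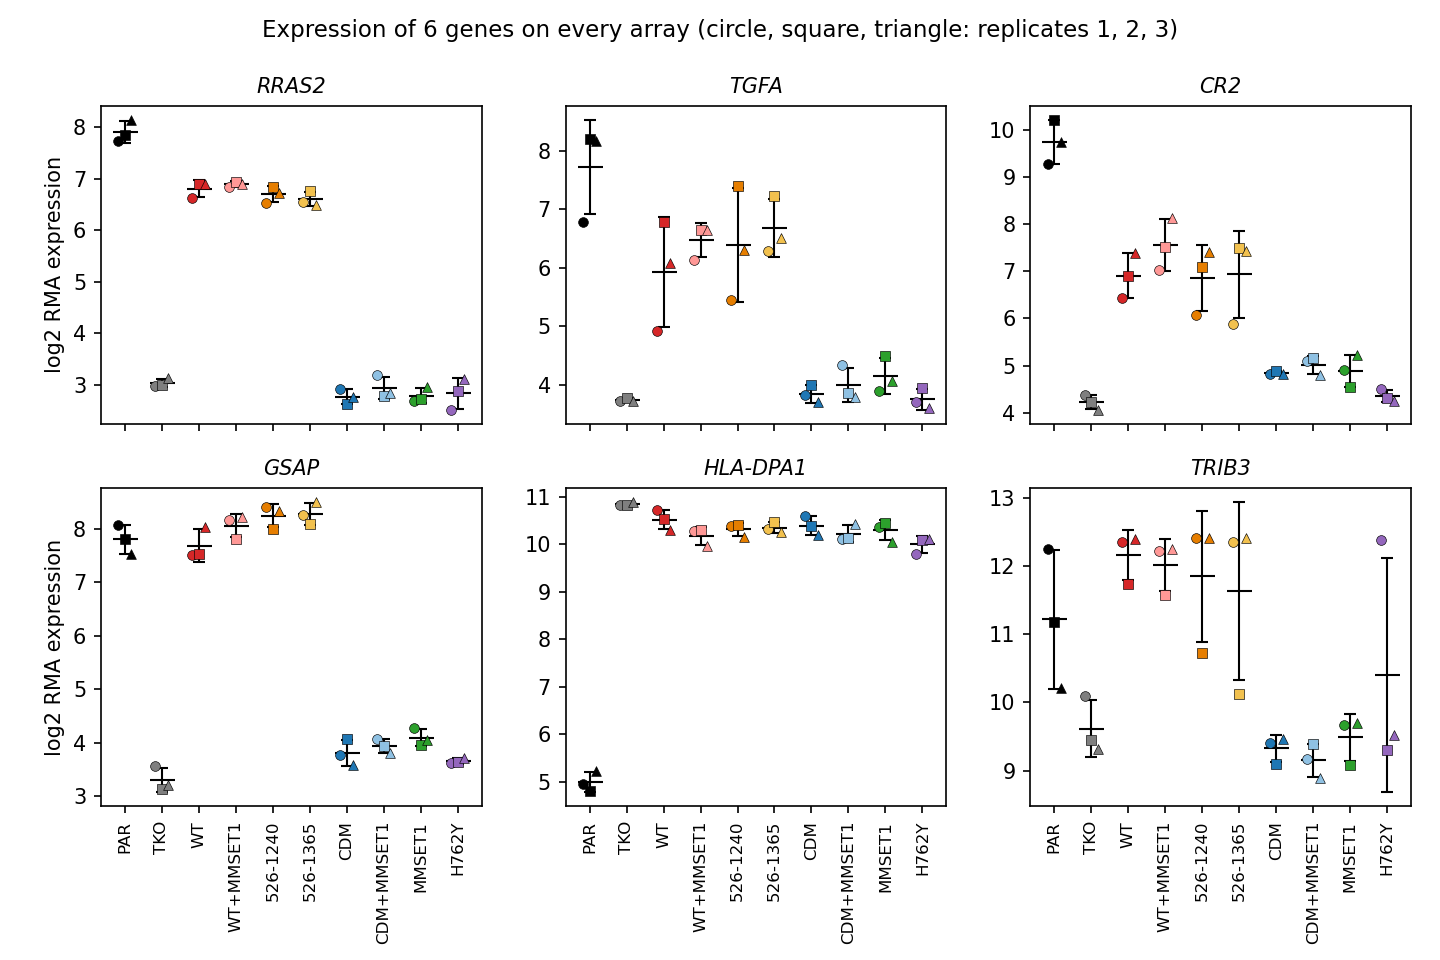
Log2 RMA expression (vertical) of 6 genes on every array by line (horizontal), with the mean as a line, error bars of 1 SD (n = 3) and symbols for replicates 1 to 3. RRAS2, TGFA, CR2 and GSAP are high in PAR and in the lines with WT or fragment NSD2, HLA-DPA1 is low in PAR alone (5.003 ± 0.214), and TRIB3 in H762Y replicate 1 (12.38) matches the WT arrays, while replicates 2 and 3 read 9.30 and 9.53.

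How far each transgene returned the knockout cells toward the parental state was measured on the 658 genes at least 2-fold higher in PAR than in TKO (median difference 1.72) and the 173 at least 2-fold lower (median -1.48). Of the 658, 546 rose in WT (83%), 563 in WT+MMSET1 (85.6%), 559 in 526-1240 (85%) and 561 in 526-1365 (85.3%). In contrast 104 rose in CDM (15.8%), 92 in H762Y (14%), 115 in MMSET1 (17.5%) and 140 in CDM+MMSET1 (21.3%). In H762Y 11 of the 658 fell, and without its replicate 1, which stood apart, 70 rose (10.6%) and 24 fell. Independent lists would share 141 rises for WT, 138 for 526-1240, 134 for 526-1365, 65.8 for CDM, 55.9 for H762Y and 61.2 for MMSET1. Of the 173 lower genes 105 fell in WT (60.7%), 104 in WT+MMSET1, 122 in 526-1240 (70.5%) and 113 in 526-1365, against 29 in CDM (16.8%), 39 in H762Y (43 without replicate 1), 34 in MMSET1 and 37 in CDM+MMSET1.

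Across all 13137 genes the change against TKO correlated with that of PAR against TKO at r = 0.713 in WT, 0.745 in 526-1240, 0.749 in 526-1365, 0.219 in CDM, 0.287 in H762Y (0.116 without replicate 1) and 0.241 in MMSET1. Genes are not independent replicates, and these comparisons share the TKO arrays. In 100 simulations, unchanged lines set against TKO gave r = 0.498 and a covariance of 0.0158, and the observed covariances were 0.275 in WT, 0.289 and 0.291 in the fragment lines, 0.0421 in CDM, 0.0549 in H762Y and 0.0467 in MMSET1. Less the simulated covariance these were 0.259 in WT, 0.273 and 0.275 in the fragment lines, 0.0263 in CDM, 0.0391 in H762Y and 0.0309 in MMSET1. The simulated arrays were independent, while replicate numbers pair PAR, CDM and MMSET1 with TKO. The small remainders of CDM and MMSET1 are therefore uncertain. Both H762Y covariances include its replicate 1, which stood apart. No split of the 3 TKO arrays leaves 2 on each side, so part of the excess of shared rises and falls over independent lists may come from the shared arrays. Comparisons that share no array with PAR against TKO do not have this limit. WT against CDM correlated with it at 0.69, WT+MMSET1 against CDM+MMSET1 at 0.666 and H762Y against WT at -0.716.

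**Figure D3:**
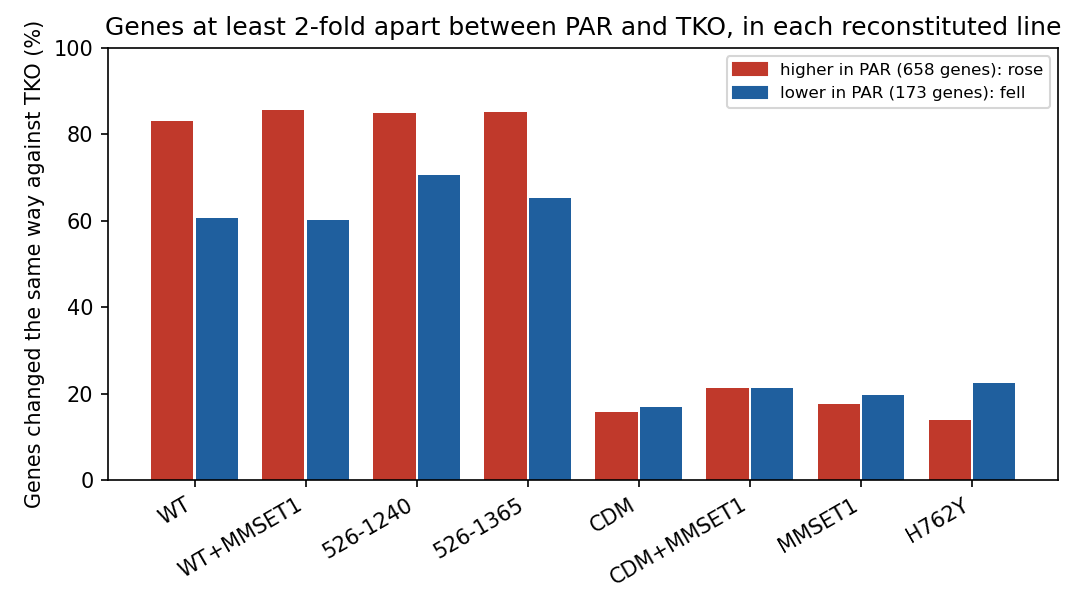
Percent (vertical) of the 658 genes higher in PAR that rose (red) and of the 173 lower genes that fell (blue) against TKO in each of the 8 reconstituted lines (horizontal). Bars of WT, WT+MMSET1 and both fragment lines reach 83% to 85.6% for the higher genes, and those of CDM, CDM+MMSET1, MMSET1 and H762Y 14% to 21.3%.

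WT against PAR shows where the reconstituted line differed from the parental line. HLA-DPA1 stood at 10.52 ± 0.204 in WT and 5.003 ± 0.214 in PAR, where it was dim (5.52, SE 0.140, adjusted p = 7.71e-19). ADTRP (5.52), P2RY10 (4.48), LAIR1 (4.37) and HLA-DQA1 (4.21) were the other largest excesses. COL4A5 (-4.17), TEX14 (-4.00), the actin-binding CAP2 (-3.83), the phospholipid-binding ANXA1 (-3.49) and the nuclear receptor NR2F1 (-3.35) were lowest. ADTRP and LAIR1 were dim in PAR, and COL4A5, CAP2, ANXA1 and NR2F1 in WT. RRAS2 was still 2.14-fold below PAR (-1.10, adjusted p = 3.44e-06) and TGFA 3.45-fold (-1.79, adjusted p = 0.00234).

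Antigen presentation genes were higher in WT than in PAR (11 rose and 1 fell of 21, with HLA-DPB1 at 3.95 and HLA-DRB1 at 2.77, 11 and 2 adjusted over the list alone, adjusted p = 3.74e-07, and adjusted p = 0.439 with an estimated correlation). Of 30 mitosis genes 14 rose and 1 fell (16 and 1 adjusted over the list alone), led by the kinesins KIF23 (1.08) and KIF11 (0.78), with NDC80 (0.89) and ECT2 (0.66). Of 33 genes of DNA replication 11 rose (12 adjusted over the list alone), among them CCNE2 (1.54), RRM2 (0.74), CDT1 (0.67) and E2F2 (0.59). The list of PRC2 and H3K27 methylation, called PRC2 here, also holds CBX genes and the demethylases KDM6A and KDM6B. Of its 14 tested genes 7 rose and 1 fell (8 and 1 adjusted over the list alone). CBX2 (0.65), RBBP4 (0.45) and EZH1 (0.45) were up and MTF2 (-0.45) down, although another MTF2 probe set was 0.435 higher. These 3 lists had adjusted p = 0.00282, 0.0411 and 0.0411. They had adjusted p = 0.647, adjusted p = 0.647 and adjusted p = 0.446 with an estimated correlation. With the replicate number as a block the mitosis list was kept (camera adjusted p = 0.000482). DNA replication (0.0541) and PRC2 (0.0506) were then not called, though the numbers did not pair all 3 arrays of these lines. EZH1 was lost without PAR replicate 2 (0.43) or 3 (0.39) and without WT replicate 1 (0.39), 2 (0.50) or 3 (0.47), and MTF2 was lost without WT replicate 1 (-0.31).

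Other lists were lower in WT than in PAR. Of 18 cholesterol synthesis genes 11 fell (13 adjusted over the list alone), led by DHCR7 (-1.56), MSMO1 (-1.54), TM7SF2 (-1.28) and HMGCS1 (-1.14). MSMO1 was lost without PAR replicate 2 (-1.15) or 3 (-1.23), and HMGCS1 without those (-0.73 and -0.85) or WT replicate 1 (-1.12). Of 29 hypoxia and glycolysis genes 10 fell and 3 rose, the same numbers adjusted over the list alone, led by ADM (-2.53), the collagen prolyl hydroxylase P4HA2 (-2.20), ENO2 (-1.82) and ALDOC (-1.29), with ADM and P4HA2 dim in WT. Of 14 genes of RAS-MAPK output 6 fell and 1 rose (6 and 2 adjusted over the list alone), led by SPRY2 (-2.15, dim in WT), ETV5 (-1.34), DUSP4 (-0.74) and ETV4 (-0.70). RRAS2 and TGFA made the list of NSD2 targets lower (2 of 3, also adjusted over the list alone). The tests gave adjusted p = 1.48e-05, 0.0167, 0.0411 and 0.0411. With an estimated correlation they gave adjusted p = 0.647, adjusted p = 0.647, adjusted p = 0.439 and adjusted p = 0.439. With the replicate block the cholesterol and hypoxia lists were kept (camera adjusted p = 4.27e-06 and 0.00922), and RAS-MAPK output (0.0506) and NSD2 targets (0.0521) were not called. In total 4021 genes (30.6%) differed, 2068 higher and 1953 lower in WT, of which 175 and 293 differed at least 2-fold. Arrays did not overlap between the lines at 4941 genes (37.6%, 10% by chance). Arrays centred on their medians gave 2559 higher and 1643 lower, averaged probe sets 1498 and 1928, and every probe set 2622 and 3019, so the balance is not settled. Leaving out PAR replicate 1 or WT replicate 2 also turned it (2261 and 2363, 1874 and 1972). A fit of these 6 arrays alone called 1926. DUSP4 read -0.48 without WT replicate 1 and HMGCS1 -1.84 without PAR replicate 1. Averaging probe sets ended the calls of EZH1 (0.11), MTF2 (-0.06) and CDT1 (0.22).

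The line with catalytically dead NSD2 was set against TKO. Without an empty vector line, effects of transduction and selection cannot be told here from those of the protein. Of the genes called, 1313 (717 higher and 596 lower) changed the same way in H762Y and MMSET1 against TKO. The reported targets were dim in both lines, RRAS2 at 2.77 ± 0.145 against 3.04 ± 0.079 (adjusted p = 0.21) and TGFA at 3.84 ± 0.149 against 3.74 ± 0.033 (adjusted p = 0.912). The largest rises were the interleukin 7 receptor IL7R (1.97), the G protein subunit GNAI1 (1.66), MAP9 (1.59), the Notch coactivator MAML3 (1.47) and RADX (1.46). IL7R, GNAI1 and MAP9 were dim in TKO and MAML3 in both lines, so of the 5 only RADX was measured on both sides. The largest falls were the receptor TNFRSF18 (-1.65), LMO7 (-1.39), PDAP1 (-1.38), the cytochrome CYP1B1 (-1.37) and HLA-DQA1 (-1.36). Of 21 antigen presentation genes 17 fell and 1 rose, the same adjusted over the list alone, with HLA-DMA at -1.06, HLA-DQB1 at -0.95 and CD74 at -0.88 (adjusted p = 8.59e-11, and adjusted p = 0.304 with an estimated correlation).

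The CDM line differed from TKO at 2256 genes (17.2%), 1313 higher and 943 lower, but at least 2-fold at 33 and 51. No overlap of arrays was seen at 5670 genes (43.2%, 10% by chance). Averaging probe sets turned the balance to 750 higher and 1045 lower, and every probe set to 1848 and 1959. Averaged, RADX rose by 0.64 and MAML3 by 0.47. With the replicate block in a fit of the 6 arrays the count was 4092, and without it 3410. It was 3613 with every probe set tested, and 1438 without TKO replicate 1.

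Active and catalytically dead NSD2 were compared in WT against CDM. Each was carried by a single line, so other differences of these lines cannot be told from the loss of activity. RRAS2 was higher in WT, 6.80 ± 0.162 against a dim 2.77 ± 0.145 (4.03, SE 0.140, adjusted p = 1.04e-15), and so was TGFA, dim in CDM (2.08, adjusted p = 0.00122). The other largest excesses were CLGN (4.92), GALNT3 (4.85), ESRP1 (4.79), THAP10 (4.49), the insulin receptor adaptor GRB10 (4.20), LINC02806 (4.17), MPPED2 (4.12), BEX4 (4.11) and the adenylyl cyclase ADCY1 (4.06). ADM was lower and dim in WT (-4.93, adjusted p = 1.65e-08), followed by OLFML2B (-3.61), the protocadherin PCDH10 (-3.34), CHRNA1 (-3.23), CLEC7A (-3.20), the synaptic protein CBLN2 (-3.02), HBD (-2.98), ERICH3 (-2.88), the Wnt pathway factor TCF7L2 (-2.76) and MYOF (-2.69). GALNT3, ESRP1, GRB10, LINC02806, MPPED2 and BEX4 were dim in CDM, and PCDH10, CHRNA1, ERICH3 and MYOF in WT. MET differed by -0.01 on its brighter probe set and was 1.55 higher on the dimmer.

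Of the 3 reported NSD2 targets tested 2 were higher in WT than in CDM, 2 adjusted over the list alone (adjusted p = 0.00927, and adjusted p = 0.0477 with an estimated correlation). The cholesterol synthesis list was lower by a median of -0.55 (adjusted p = 0.0491, and adjusted p = 0.904 with an estimated correlation), though SQLE (-1.39) was the single member of 18 that fell, and 0 fell adjusted over the list alone. In total 3070 genes (23.4%) differed, 1625 higher and 1445 lower in WT, with 541 and 150 at least 2-fold. The balance turned with averaged probe sets (1358 higher, 1478 lower), every probe set (1770 and 1794), centred arrays (1517 and 1653), the stricter filter (1354 and 1470), without the apart H762Y array (2059 and 2082) and without WT replicate 2 (1582 and 1619). Averaged, TGFA was 0.72 higher, ADCY1 1.42 and GALNT3 2.48. The groups did not overlap at 5697 genes (43.4%, 10% by chance). Of the 658 genes higher in PAR than in TKO, 497 (75.5%) were higher in WT than in CDM. The count varied with the arrays kept. It was 1546 without WT replicate 1, 3201 without WT replicate 2 and 1920 without WT replicate 3. Without CDM replicates 1, 2 and 3 in turn it was 1944, 2084 and 1620. Of the 1546 genes called without WT replicate 1, 1498 were among the 3070. MYOF was not called without WT replicate 1 (-2.53) or 3 (-2.35), and SQLE (-1.26 to -1.42) was called only when all 3 arrays of CDM and WT replicates 1 and 3 were kept.

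**Figure D4:**
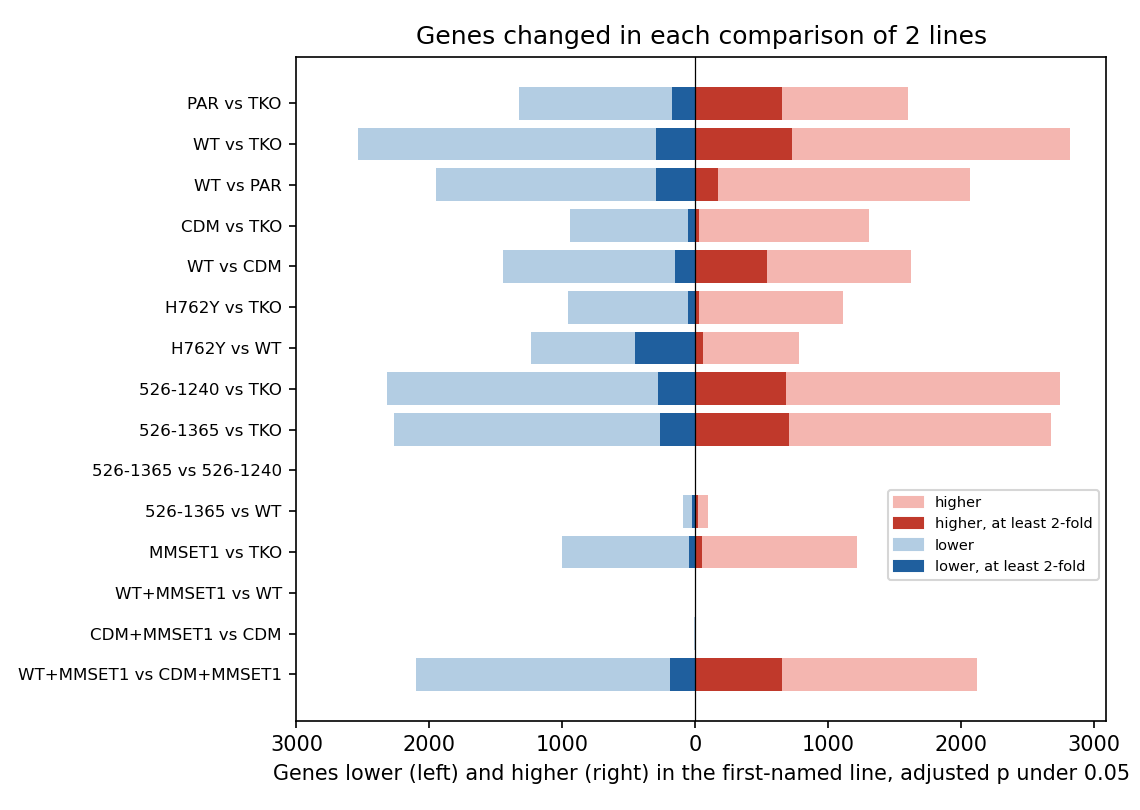
Numbers of genes lower (left, blue) and higher (right, red) in the first-named line of each of 15 comparisons (vertical) at an adjusted p under 0.05, with dark parts for changes of at least 2-fold. WT and both fragment lines have 4949 to 5364 genes against TKO, CDM, H762Y and MMSET1 2070 to 2256, and adding MMSET I to WT or CDM 2 and 6.

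The H762Y line was first set against TKO. RRAS2 read 2.84 ± 0.303 in H762Y and 3.04 ± 0.079 in TKO (adjusted p = 0.376), and TGFA 3.75 ± 0.177 and 3.74 ± 0.033 (adjusted p = 0.991), all dim. TNFRSF18 fell 4.4-fold (-2.14, SE 0.168, adjusted p = 5.23e-08), followed by HSPB1 (-1.71), LMO7 (-1.60), HLA-DQA1 (-1.58) and HLA-DMA (-1.56). The largest rises were ERMN (1.45), SLC18B1 (1.39), MAP9 (1.39), SLITRK5 (1.33) and the circadian repressor NR1D2 (1.30), with MAP9 and SLITRK5 dim in TKO. Of 21 antigen presentation genes 16 fell and 1 rose (17 and 1 adjusted over the list alone), with HLA-DQB1 (-1.27) and HLA-DPB1 (-1.18) among them (adjusted p = 1.92e-14, and adjusted p = 0.191 with an estimated correlation).

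In H762Y 2070 genes (15.8%) differed from TKO, 1116 higher and 954 lower, with 32 and 51 at least 2-fold. Arrays did not overlap between the lines at 3990 genes (30.4%, 10% by chance). Averaging probe sets turned the balance to 688 higher and 1026 lower, every probe set to 1741 and 2010, and the fit of the 6 arrays to 128 and 167. H762Y replicate 1 stood apart from the other two arrays of its line. Without it the count was 2287, with 1484 genes shared, and ERMN (1.29), NR1D2 (0.78) and HSPB1 (-1.27) were no longer called. Without TKO replicate 1 the count was 1303, and ERMN was lost without any 1 of the 6 arrays (1.29 without H762Y replicate 1, 1.68 without TKO replicate 1). A fit of the 6 arrays alone called 295, and 0 with the replicate block in that fit (limma), although the numbers do not pair these lines. With every probe set tested the count was 3564.

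The H762Y line was then set against WT. Each protein was carried by a single line, so other differences of these lines cannot be told from an effect of the substitution. RRAS2 was lower and dim in H762Y, 2.84 ± 0.303 against 6.80 ± 0.162 (-3.96, SE 0.140, adjusted p = 1.53e-15), and so was TGFA (-2.17, adjusted p = 0.000943). MPPED2 (-4.21), GSAP (-4.04), ADCY1 (-4.00) and GALNT3 (-3.85) were the other lowest genes, and of these MPPED2, GSAP and GALNT3 were dim in H762Y too. ADM was higher in H762Y and dim in WT (4.59, SE 0.437, adjusted p = 4.82e-08), followed by CLEC7A (2.80), PCDH10 (2.60), CBLN2 (2.46) and TCF7L2 (2.40), with PCDH10 dim in WT. MET differed by 0.02 on its brighter probe set and fell by 1.55 on the dimmer.

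Of 3 reported NSD2 targets tested 2 fell in H762Y relative to WT, 2 adjusted over the list alone (adjusted p = 0.00258, and adjusted p = 0.0326 with an estimated correlation). Of 18 p53 targets 5 fell and 1 rose, the same adjusted over the list alone, led by the membrane protein PERP (-2.92), and of 27 adhesion genes 9 fell and 2 rose (11 and 2 adjusted over the list alone), led by EPCAM (-2.02), ALCAM (-1.86), CDH2 (-1.66) and ITGA2 (-1.28), of which ALCAM and CDH2 were dim in H762Y and ITGA2 in both lines. Both lists had adjusted p = 0.0363 and adjusted p = 0.474 with an estimated correlation. SESN2 (-2.16), TP53INP1 (-2.13) and TNFRSF10B (-1.57), the other leading p53 targets, are also induced in amino acid and endoplasmic reticulum stress. The 3 were lost without H762Y replicate 2 (-1.33, -1.53 and -1.17), H762Y replicate 3 (-1.82, -1.59 and -1.14), WT replicate 1 (-2.19, -2.09 and -1.44) or WT replicate 3 (-2.14, -2.20 and -1.50), and TP53INP1 also without WT replicate 2 (-2.11). Without H762Y replicate 1 they were -3.32, -3.29 and -2.41. On H762Y replicate 1 SESN2 read 10.67, against 6.69 and 7.66 in replicates 2 and 3. Of 21 antigen presentation genes 6 fell, among them HLA-DMB (-0.68), HLA-F (-0.58), HLA-DPA1 (-0.52) and HLA-DPB1 (-0.48) (10 adjusted over the list alone, adjusted p = 0.00258, and adjusted p = 0.704 with an estimated correlation). The mitosis list was lower, with NUSAP1 (-0.53), CDK1 (-0.48) and CCNB2 (-0.46) down and CDC20 (0.41) up of 30 (9 and 1 adjusted over the list alone, adjusted p = 0.00609, and adjusted p = 0.704 with an estimated correlation). The cholesterol list was higher, with PMVK (0.81) the single member of 18 that rose, 1 adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.733 with an estimated correlation).

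In total 2021 genes (15.4%) differed between H762Y and WT, 785 higher and 1236 lower in H762Y, with 60 and 455 at least 2-fold. No overlap of arrays was seen at 2362 genes (18%, 10% by chance). Replicate 1 of H762Y set this count: without it 5147 genes passed (2550 higher, 2597 lower), 1971 of the 2021 among them, and 0 of 28 named genes lost their limma call. WT replicate 1 carried the calls of HLA-F (-0.48 without it), HLA-DPA1 (-0.42), HLA-DPB1 (-0.42), NUSAP1 (-0.40), CDK1 (-0.34), CCNB2 (-0.35) and PMVK (0.64). HLA-F, HLA-DPB1, NUSAP1, CCNB2, PMVK and CDC20 were lost without H762Y replicate 2 (-0.44, -0.51, -0.42, -0.39, 0.65 and 0.33) or 3 (-0.46, -0.51, -0.43, -0.40, 0.65 and 0.40), HLA-F, NUSAP1 and CDC20 without WT replicate 3 (-0.55, -0.59 and 0.31) and CDC20 without WT replicate 2 (0.43). Averaging probe sets ended the calls of NUSAP1 (-0.53), CCNB2 (-0.11) and HLA-DPA1 (-0.34) and gave RRAS2 -2.60, TGFA -0.73 and PERP -1.26. Without replicate 2 or 3 the count was 712 or 738, and without WT replicate 1 it was 1060. It was 303 in a fit of the 6 arrays alone. Of the list calls, those of NSD2 targets, mitosis, p53 targets, antigen presentation and cholesterol synthesis were kept without H762Y replicate 1 (adjusted p = 0.0181, 0.0181, 0.0181, 0.0168 and 0.00184), and that of adhesion was not (adjusted p = 0.314). The NSD2 target list then had adjusted p = 0.272 with an estimated correlation.

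The fragment of residues 526 to 1240 was set against TKO. RRAS2, dim in TKO, rose to 6.70 ± 0.155 (3.66, SE 0.140, adjusted p = 2.31e-15), and TGFA, also dim there, to 6.38 ± 0.974 (2.64, adjusted p = 2.99e-05). The largest rises were CLGN (5.36, 41-fold), GSAP (4.95), SLC6A15 (4.56), MPPED2 (4.50) and THAP10 (4.47), and the largest falls ADM (-5.00), OLFML2B (-4.60), CLEC7A (-4.42), HBD (-3.62) and the synaptic protein SYNDIG1 (-3.42). GSAP, SLC6A15 and MPPED2 were dim in TKO and ADM in 526-1240. Of 21 antigen presentation genes 13 fell and 3 rose (14 and 3 adjusted over the list alone), with HLA-DQA1 (-1.81), HLA-DMA (-1.22), the class II transactivator CIITA (-1.22) and CD74 (-1.04) lowest. Of 18 cholesterol synthesis genes 8 fell and 1 rose, the same adjusted over the list alone, with LSS (-1.56), TM7SF2 (-1.33), PMVK (-1.21) and IDI1 (-0.91) lowest. Of 3 NSD2 targets 2 rose, 2 adjusted over the list alone. The tests gave adjusted p = 0.00065, 0.0141 and 0.014. The same lists had adjusted p = 0.664, adjusted p = 0.664 and adjusted p = 0.0957 with an estimated correlation. In total 5066 genes (38.6%) changed, 2746 higher and 2320 lower, with 687 and 280 at least 2-fold. The groups did not overlap at 6618 genes (50.4%, 10% by chance). Averaging probe sets turned the balance to 2123 higher and 2511 lower and put TGFA at 0.92, and every probe set gave 3373 and 3501. IDI1 was lost without any of the TKO arrays (-0.88, -0.87 and -0.99 for replicates 1 to 3) or 526-1240 replicate 1 (-0.89) or 3 (-0.78).

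The fragment of residues 526 to 1365 gave RRAS2, dim in TKO, at 6.60 ± 0.140 (3.57, SE 0.140, adjusted p = 3.38e-15) and TGFA, also dim there, at 6.67 ± 0.493 (2.93, adjusted p = 7.82e-06). CLGN (5.20), GSAP (4.98), MPPED2 (4.65), SLC6A15 (4.62) and FOXP2 (4.60) rose most, and ADM (-4.97), OLFML2B (-4.07), CLEC7A (-4.06), CBLN2 (-3.49) and SYNDIG1 (-3.21) fell most. GSAP, MPPED2, SLC6A15 and FOXP2 were dim in TKO, and ADM and CBLN2 in 526-1365. Antigen presentation genes fell at 12 of 21 and rose at 2 (13 and 3 adjusted over the list alone), including HLA-DQA1 (-1.73), HLA-DMA (-1.23), CIITA (-1.09) and HLA-DQB1 (-1.01). Of 18 cholesterol synthesis genes 7 fell and 1 rose (8 and 1 adjusted over the list alone), including LSS (-1.60), TM7SF2 (-1.26), PMVK (-1.13) and IDI1 (-0.97), and 2 of 3 NSD2 targets rose, 2 adjusted over the list alone. The tests gave adjusted p = 0.000658, 0.0162 and 0.0173. With an estimated correlation they gave adjusted p = 0.56, adjusted p = 0.71 and adjusted p = 0.144. In total 4949 genes (37.7%) changed, 2680 higher and 2269 lower, with 711 and 261 at least 2-fold. Arrays did not overlap between the lines at 6577 genes (50.1%, 10% by chance). Averaging probe sets turned the balance to 2022 higher and 2511 lower and put TGFA at 1.05, every probe set gave 3300 and 3489, and centred arrays 2460 and 2526. IDI1 was lost without any of the TKO arrays (-0.94, -0.93 and -1.05 for replicates 1 to 3) or 526-1365 replicate 1 (-0.85) or 3 (-0.87).

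The part after residue 1240, which holds the last PHD finger, was assessed by setting 526-1365 against 526-1240. No gene differed: limma called 0 of 13137, with 180 at an unadjusted p under 0.05, and 0 with the replicate block. The 3 arrays of each line did not overlap at 590 genes (4.49%, against 10% by chance for unpaired arrays). The replicate numbers pair these lines, which makes overlap more likely, so this share does not show that the lines are more alike than chance. NSD2 was the exception when every probe set was tested, with 1 gene called, and its probe set 209052_s_at was 1.77 higher in 526-1365. The mitosis list was lower in 526-1365 by a median of -0.125, with 0 of 30 members called by limma, 0 adjusted over the list alone (adjusted p = 9.16e-07, and adjusted p = 0.717 with an estimated correlation). A missed threshold does not show that the fragments act alike.

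The part before residue 526 was assessed by setting 526-1365 against WT. MARCKS, an actin-regulating substrate of protein kinase C, was lower in 526-1365, a dim 3.44 ± 0.493 against 7.50 ± 0.198 (-4.06, SE 0.267, adjusted p = 8.07e-10). RND3 (-2.03), SCRN3 (-1.91), MAML2 (-1.90) and C11orf96 (-1.66) were the next lowest. The Notch ligand DNER was higher in 526-1365 and dim in WT (3.37, SE 0.394, adjusted p = 1.68e-05), followed by the cadherin CDH17 (3.13), the interleukin 2 receptor chain IL2RB (1.93), OVAAL (1.89) and the chemokine CCL5 (1.84). RND3 and SCRN3 were dim in 526-1365, and CDH17 and OVAAL in WT. Lists of mitosis (median -0.184) and of the unfolded protein response (median -0.221) were lower with 0 of 30 and 0 of 25 members called by limma, 0 and 1 adjusted over the list alone (adjusted p = 0.000413 and 0.00344). With an estimated correlation both had adjusted p = 0.972.

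In total 186 genes (1.42%) differed between 526-1365 and WT, 98 higher and 88 lower in 526-1365, with 21 and 20 at least 2-fold. No overlap of arrays was seen at 1782 genes (13.6%, 10% by chance). The replicate numbers pair these lines. With the replicate block 399 genes passed, and in the paired fit of the 6 arrays 250, with 103 of the 186 among them. Centred arrays turned the balance to 85 higher and 113 lower, the stricter filter to 80 and 86, and leaving out WT replicate 1 or 526-1365 replicate 2 to 55 and 69 or 54 and 56. Averaging probe sets put MARCKS at -2.05. The count was 110 without 526-1365 replicate 2 or 3, 123 without WT replicate 3, 304 without the apart H762Y array and 23 in a fit of the 6 arrays alone. MAML2 was not called without 526-1365 replicate 2 (-1.49) or WT replicate 3 (-1.78).

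The short isoform MMSET I alone was set against TKO. RRAS2 read 2.79 ± 0.146 against 3.04 ± 0.079 (adjusted p = 0.248) and TGFA 4.15 ± 0.309 against 3.74 ± 0.033 (adjusted p = 0.583), all dim. RADX rose 4.27-fold (2.10, SE 0.116, adjusted p = 3.96e-11), followed by MAP9 (1.92), the cyclophilin PPIC (1.83), MAML3 (1.66) and SPART (1.66). GRB10 (-1.83), TNFRSF18 (-1.66), CYP1B1 (-1.63), HLA-DQA1 (-1.61) and MARCKS (-1.49) fell most. MAP9 and SPART were dim in TKO, GRB10 and MARCKS in MMSET1 and MAML3 in both lines. Antigen presentation genes fell at 17 of 21 and rose at 1, the same adjusted over the list alone, with HLA-DMA (-1.06), HLA-DQB1 (-0.97) and CIITA (-0.97) among them (adjusted p = 1.20e-10, and adjusted p = 0.495 with an estimated correlation). In total 2220 genes (16.9%) changed, 1221 higher and 999 lower, with 51 and 44 at least 2-fold. The groups did not overlap at 5200 genes (39.6%, 10% by chance). Averaging probe sets turned the balance to 724 higher and 1037 lower and put RADX at 1.03, and every probe set gave 1690 and 1943. The count was 3333 with the replicate block in a fit of the 6 arrays, 3461 with every probe set tested and 1434 without TKO replicate 1.

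What MMSET I adds to active NSD2 was read from WT+MMSET1 against WT. PROS1, the anticoagulant protein S, rose 1.92-fold, from 5.99 ± 0.306 to 6.93 ± 0.115 (0.94, SE 0.161, adjusted p = 0.0357). The collagen chain COL4A5 read 3.49 ± 0.241 in WT and 4.50 ± 0.376 in WT+MMSET1 (adjusted p = 0.0201), both dim, so a change of its RNA is not measured. These 2 were the genes called of 13137, with 366 at an unadjusted p under 0.05. Arrays did not overlap between the lines at 868 genes (6.61%, 10% by chance for unpaired arrays). RRAS2 (0.09) and TGFA (0.55) did not pass (adjusted p = 1 for both), TGFA standing at 0.05 without WT replicate 1 and 0.98 without WT replicate 2. The replicate numbers pair these lines. With the replicate block COL4A5 was the 1 gene called, and 0 passed in a fit of the 6 arrays with or without the block (limma). Leaving out an array gave 0 (WT replicate 1, WT+MMSET1 replicate 1 or 2) or 1 (WT replicate 2 or 3, WT+MMSET1 replicate 3), and averaging probe sets gave 0. COL4A5 was lost without WT replicate 1 (0.92) or 3 (0.97) or WT+MMSET1 replicate 1 (0.87) or 2 (0.93). PROS1 was lost without WT replicate 1 (0.77) or 2 (0.98) or WT+MMSET1 replicate 1 (0.89), 2 (0.93) or 3.

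Small shifts of lists without a single called member also passed between WT+MMSET1 and WT. Mitosis (median -0.175, adjusted p = 5.18e-10), DNA replication (-0.0778, adjusted p = 0.00106) and antigen presentation (-0.0779, adjusted p = 0.00104) were lower. RAS-MAPK output (0.136, camera adjusted p = 0.026) and the reference set of ribosomal proteins (0.0399, adjusted p = 0.0041) were higher. None held with an estimated correlation, with adjusted p = 0.516 for mitosis and RAS-MAPK output and adjusted p = 0.638 for the other 3. In each list limma called 0 members, 0 adjusted over the list alone. Because the reference set also passed at so small a shift, the calls of the other lists here are uncertain.

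What MMSET I adds to dead NSD2 was read from CDM+MMSET1 against CDM. The phosphatase PTPRF fell by 0.57 (9.23 ± 0.058 against 9.80 ± 0.132, adjusted p = 0.0182), and the sterol exporter ABCG1 and the phosphodiesterase SMPDL3A by 1.17 each, and GLMP (-0.72) and the kinase MARK1 (-0.62) fell too. RADX rose by 0.62 (adjusted p = 0.0459). These 6 genes were called of 13137, 1 higher and 5 lower, with 634 at an unadjusted p under 0.05. No overlap of arrays was seen at 3185 genes (24.2%, 10% by chance). DNA replication genes were higher by a median of 0.124 (camera adjusted p = 4.12e-05), and the reference set of ribosomal proteins was lower by -0.0543 (adjusted p = 0.000606). In both lists 0 members were called by limma, 0 adjusted over the list alone. Both had adjusted p = 0.686 with an estimated correlation. Leaving out CDM replicate 1 or 2 or CDM+MMSET1 replicate 3 gave 0 genes (limma), leaving out CDM+MMSET1 replicate 1 gave 1, and leaving out CDM+MMSET1 replicate 2 or CDM replicate 3 gave 4. Averaging probe sets ended all 6 calls. The count was 10 with arrays centred on their medians, 40% of them higher instead of 16.7%. It was 17 without the apart H762Y array, 3 without the filter or with trended variances, and 2 with averaged probe sets. A fit of the 6 arrays alone gave 50, and 0 with the replicate block in that fit (limma), although the numbers do not pair these lines.

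The catalytic activity beside MMSET I was read from WT+MMSET1 against CDM+MMSET1. RRAS2 was higher, 6.89 ± 0.055 against a dim 2.94 ± 0.220 (3.95, SE 0.140, adjusted p = 1.65e-15), and so was TGFA, dim in CDM+MMSET1 (2.48, adjusted p = 0.000155). GALNT3 (4.68), the activin chain INHBE (4.62), ADCY1 (4.52), ESRP1 (4.37) and the stress-induced transcription factor ATF3 (4.36) were highest, and ADM (-4.62), MYOF (-4.29), ERICH3 (-3.42), PCDH10 (-3.37) and OLFML2B (-3.14) lowest. GALNT3, ADCY1 and ESRP1 were dim in CDM+MMSET1, and ADM, MYOF and ERICH3 in WT+MMSET1. Of 18 p53 targets 6 rose and 2 fell, the same adjusted over the list alone, led by SESN2 (3.36), PERP (3.34), TP53INP1 (2.58) and TNFRSF10B (2.48), and 2 of 3 NSD2 targets rose, 2 adjusted over the list alone. Both lists had adjusted p = 0.0267. They had adjusted p = 0.527 and adjusted p = 0.122 with an estimated correlation. MET differed by -0.08 on its brighter probe set and was higher on the dimmer.

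In total 4219 genes (32.1%) differed between WT+MMSET1 and CDM+MMSET1, 2120 higher and 2099 lower, with 654 and 187 at least 2-fold. The groups did not overlap at 6968 genes (53%, 10% by chance). The balance turned with averaged probe sets (1737 higher, 2300 lower), every probe set (2412 and 2799), centred arrays (1921 and 2397), the stricter filter (1813 and 2023) and without the apart H762Y array (2460 and 2474). Averaged, TGFA was 0.83 higher and PERP 1.33. The count was 2526 without WT+MMSET1 replicate 1. Of the 658 genes higher in PAR than in TKO, 496 (75.4%) were higher here.

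Whether the effect of MMSET I depends on the NSD2 beside it was tested as the difference of its effects in WT and CDM. No gene passed: limma called 0 of 13137, with 492 at an unadjusted p under 0.05. RRAS2 (-0.08, SE 0.198) and TGFA (0.39, SE 0.592) had adjusted p = 1, TGFA standing at -0.11 without WT replicate 1 and 0.82 without WT replicate 2. Lists of DNA replication (median -0.184, camera adjusted p = 1.83e-08) and mitosis (-0.163, adjusted p = 8.56e-05) were lower. The reference set of ribosomal proteins (0.0998, adjusted p = 1.62e-06) and the MAF program of myeloma (0.452, adjusted p = 0.047) were higher. In these lists 0 members were called, 0 adjusted over the list alone. With an estimated correlation they had adjusted p = 0.392, adjusted p = 0.787, adjusted p = 0.392 and adjusted p = 0.773. Leaving out WT+MMSET1 replicate 3 gave 1 gene.

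Across the 16 comparisons 47 of 464 list tests passed with the preset correlation. With an estimated correlation 3 held, those of the NSD2 targets in PAR against TKO, WT against CDM and H762Y against WT. All 3 rest on RRAS2 and TGFA, the called members of a short list. That of H762Y against WT had camera adjusted p = 0.272 without H762Y replicate 1. Among the lists called in no comparison were those of enzymes that add or remove H3K36 methylation, t(4;14) myeloma, plasma cell identity and the earlier B cell program. Lists of extracellular matrix, TGF-beta signalling, the BCL2 family, type I interferon and cancer-testis genes (2 of 21 tested) were not called either.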

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

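The splits of arrays were fixed before the results were seen, and of the tests of 3 patterns below, 4 were written after a result was seen, as marked. The list used in the ATF4 test was written after other ATF4 targets had been seen. No result met the fixed rules for a surprise: groups of 3 arrays were not tested for outliers, and the interaction gave 0 genes (limma), with 492 at an unadjusted p under 0.05.

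H762Y replicate 1 stands apart from replicates 2 and 3, and the cause may lie in the culture. Under a wrong label from another of the 9 groups it should correlate with that group as its members do, but its lowest correlation with the closest, WT+MMSET1, was 0.976 against 0.9911 within that group, which argues against this (test written after the result was seen, and a sample from outside the series stays open). A mixture with RNA of an active line should raise all WT-specific genes alike, but 36% of 203 reached under 10% of the WT excess while 34.5% exceeded 50%, which argues against it (written after an earlier test, fixed beforehand, had not excluded a mixture, with 1 gene outside the range against up to 2 on other arrays). A stress state of that culture could raise ATF4 targets, and 29 of 29 further targets were higher in replicate 1, by a median of 1.37 (list written before its values were read, after 10 other targets were seen). Their mean in replicate 1 was 10.76, within the 10.34 to 10.95 of the lines with WT or fragment NSD2 and the 10.19 to 11.03 of PAR. The rise therefore does not tell a stress state from a WT-like level of these genes. RRAS2 (2.52) and GSAP (3.62) stayed at the knockout level in replicate 1, but GALNT3 (5.98 against 3.28 and 3.43 in replicates 2 and 3), ADM (7.65 against 9.87 and 9.87) and PERP (8.09 against 7.25 and 7.42) lay nearer WT.

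HLA class II genes are lower in PAR than in TKO (median 2.58), and signal shared between paralogs might cause this. Of CD74, CIITA, HLA-DMA, HLA-DMB and HLA-DRA, 5 of 5 were lower in PAR by at least 1 log2 unit, which argues against it (written after the result was seen). Monocyte RNA in TKO cultures could raise class II genes, but the markers differed by a median of 0.01 (fixed beforehand), which argues against it. If loss of catalytic activity alone raised the genes, its return should lower them, but WT differed from CDM by a median of 0.012 (written after an earlier version, the share taken back in WT, 28.2%, had lain between its bounds). A difference of the knockout clone, or a switch that re-expression does not reverse, might explain the pattern, and neither was tested.

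Lines with CDM, H762Y and MMSET I alone differ from TKO at 1313 common genes, in comparisons that share the TKO arrays. Remaining NSD2 activity in these lines could shift the genes farther with active NSD2, and the active line that shifts farthest moved 1.06 times as far (fixed beforehand), but the genes were selected in the 3 lines and all shifts share the TKO arrays, so this ratio leaves the explanation open. A state of the TKO cultures or arrays alone should shift PAR as far, and PAR shifted 24.4% as far (21.3 to 28), which cannot tell the explanations apart (fixed beforehand). Passage through transduction and selection could also shift these genes, and no line with an empty vector is among the groups analysed here. Between the lines 1 gene differed in CDM against MMSET1 (limma, 257 at an unadjusted p under 0.05), 7 in H762Y against CDM and 14 in H762Y against MMSET1, and without H762Y replicate 1 these were 4, 34 and 38.

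Each comparison of 3 with 3 arrays has 10 splits, which cannot give a share under 0.05. The real grouping alone reached its count (value 1) in PAR against TKO (2928, highest other 0), WT against TKO (5364, 0), WT against PAR (4021, 1547), CDM against TKO (2256, 0), WT against CDM (3070, 1), H762Y against TKO (2070, 973), 526-1240 against TKO (5066, 0), 526-1365 against TKO (4949, 0), 526-1365 against WT (186, 1), MMSET1 against TKO (2220, 0), CDM+MMSET1 against CDM (6, 0) and WT+MMSET1 against CDM+MMSET1 (4219, 0). In H762Y against WT 3 of 10 splits reached 2021, the highest 3707, and in WT+MMSET1 against WT 2 of 10 reached 2, the highest 24, which points to a structure of the samples. Where the real count is 0 every split reaches it by construction, so the values of 526-1365 against 526-1240 (10 of 10) and of the interaction (100 of 100) test nothing. The highest counts there were 2 and 3624 (limma), the latter in splits that mix WT with CDM lines.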

How the results depend on the processing

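The alternatives were fixed before the data were examined, except the fit without H762Y replicate 1 and the fit of 2 lines with the replicate block, which were chosen after seeing the data. Signal over background limits what is seen of dim genes, and 3 arrays per line limit the precision. No named gene or list changed sign past the threshold in the settings tried, but 9 of 179 named gene results with several probe sets had a probe set that passed in the opposite direction. The balance of higher and lower genes turned with averaged probe sets in 10 comparisons. For a count that moved by more than 1.5-fold the cause was not tested. The correlations with PAR against TKO kept their values within leave-one-out ranges of 0.574 to 0.752 (WT against CDM), -0.761 to -0.624 (H762Y against WT) and 0.556 to 0.73 (WT+MMSET1 against CDM+MMSET1). Each was weakest without PAR replicate 1 and strongest without PAR replicate 3.

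Fits of the compared arrays alone called 1926 genes in WT against PAR, 3410 in CDM against TKO, 295 in H762Y against TKO, 303 in H762Y against WT, 23 in 526-1365 against WT, 0 in WT+MMSET1 against WT (limma) and 50 in CDM+MMSET1 against CDM. Testing every probe set gave 3613 in CDM against TKO, 3564 in H762Y against TKO, 3461 in MMSET1 against TKO, 1 in 526-1365 against 526-1240 and 1 in WT+MMSET1 against WT. Averaging probe sets gave 0 in WT+MMSET1 against WT and 2 in CDM+MMSET1 against CDM. In CDM+MMSET1 against CDM no filter gave 3, trended and robust variances 3 and centring 10. Without H762Y replicate 1 in the fit H762Y against WT gave 5147, 526-1365 against WT 304 and CDM+MMSET1 against CDM 17.

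The replicate block gave 3424 in H762Y against WT, 399 in 526-1365 against WT, 1 in WT+MMSET1 against WT and 17 in CDM+MMSET1 against CDM. The replicate block in fits of the 2 lines alone gave 4092 in CDM against TKO, 0 in H762Y against TKO, 429 in H762Y against WT, 3333 in MMSET1 against TKO, 0 in WT+MMSET1 against WT and 0 in CDM+MMSET1 against CDM (limma). Of the 47 list tests passed, the replicate block ended 6, those of RAS-MAPK output and NF-kB targets in PAR against TKO and of PRC2 (adjusted p = 0.0506 with the block), NSD2 targets (0.0521), RAS-MAPK output (0.0506) and DNA replication (0.0541) in WT against PAR. In WT against PAR the residuals of equal-numbered arrays correlated at 0.55, 0.47 and -0.21, so the numbers did not pair all 3 arrays. Of 300 named gene results it ended the call of PROS1 in WT+MMSET1 against WT and added that of NSD2 in MMSET1 against TKO, and the block changed no other call. It turned the balance to 2102 higher and 2199 lower in WT against CDM, where the numbers do not pair but every array correlated best with its own number, and to 2535 and 2584 in WT+MMSET1 against CDM+MMSET1. An estimated correlation ended 44 of the 47.

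Leaving out each array gave 1438 to 1887 genes in CDM against TKO (lowest without TKO replicate 1), 1546 to 3201 in WT against CDM (lowest without WT replicate 1), 1303 to 2287 in H762Y against TKO (lowest without TKO replicate 1), 712 to 5147 in H762Y against WT (lowest without H762Y replicate 2, highest without replicate 1), 110 to 186 in 526-1365 against WT, 1434 to 1860 in MMSET1 against TKO, 0 to 1 in WT+MMSET1 against WT, 0 to 4 in CDM+MMSET1 against CDM, 2526 to 3791 in WT+MMSET1 against CDM+MMSET1 and 0 to 1 in the interaction (limma).

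Of the named gene results, called or not, leaving out an array ended a call in 118 tests, added a call in 1 and kept the side of the threshold in 1705. Fits of the compared arrays alone ended 35 of 300, no filter 6, every probe set 4, trended and robust variances 3 and the fit without H762Y replicate 1 3. Averaged probe sets ended 15 and kept 263, and the stricter filter added 1 call and kept 268. The remaining results had no value in those settings. Centring ended none.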

Other observations

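The list of ATF4 targets used here was chosen after the result was seen, in WT against CDM and in H762Y replicate 1. ATF4 is the transcription factor of the integrated stress response.

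Of 29 ATF4 targets tested 27 rose in WT against CDM (median 1.27, adjusted p = 1.30e-15, and adjusted p = 0.516 with an estimated correlation) and 28 rose in WT+MMSET1 against CDM+MMSET1 (median 1.40, adjusted p = 2.80e-17, and adjusted p = 0.516 with an estimated correlation). Against TKO 18 rose in WT (median 0.81) and 7 in PAR (median 0.50), while in CDM 1 rose and 2 fell (median -0.41). The list also differed between lines without active NSD2. In CDM+MMSET1 against CDM its median was -0.32 with 0 members called (camera adjusted p = 6.08e-08, and adjusted p = 0.69 with an estimated correlation). The per-array means were 9.36 to 10.17 in TKO, 10.19 to 11.03 in PAR and 8.78 to 9.77 in CDM, CDM+MMSET1 and MMSET1. In WT, WT+MMSET1 and the fragment lines they were 10.34 to 10.95. They fell with the replicate number in PAR (11.03, 10.72 and 10.19), TKO (10.17, 9.97 and 9.36), CDM, MMSET1 and CDM+MMSET1. No such order was seen in WT, WT+MMSET1, the fragment lines or H762Y. H762Y read 10.76, 9.12 and 9.30. Active NSD2 might raise this program, through higher demand for amino acids, or the cultures could have differed in nutrients at harvest. In H762Y replicate 1 29 of 29 further targets stood higher by a median of 1.37 while RRAS2 stayed at 2.52, but this is 1 array, and GALNT3 (5.98) and ADM (7.65) lay nearer WT in it. Measuring ATF4 protein and amino acids in medium of matched cultures would part these.

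The genes HLA-DPA1, ADTRP, P2RY10 and LAIR1 separated PAR from TKO and WT alike, and differed by 5.52, 5.52, 4.48 and 4.37 between WT and PAR. A clonal difference of the knockout line could produce this, and so could a switch that re-expression does not reverse. Neither was tested. The median WT minus CDM difference of 0.012 covers class II genes, among them HLA-DPA1 but not ADTRP, P2RY10 or LAIR1, and does not tell these explanations apart. Other knockout clones, or sequencing of HLA class II regulators, would test the clonal difference.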
